A study of Mus musculus with 64 samples.

How the data were processed

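RNA from microdissected inner ear epithelium and from the surrounding tissue of CBA/J embryos was measured on 64 Affymetrix arrays, 1 array per pool of tissues and 2 pools from different litters per group, in 29 inner ear groups and 3 groups of non-inner ear tissue. Pools hold 6 to 17 tissues per the labels, which give no number for 4 of the non-inner ear arrays, and 4 to 17 per the series text. Tissue was freed in dispase for 8 to 10 minutes at E9 to E10.5 and 20 to 25 minutes at E11 to E15, and RNA was labelled as biotinylated cRNA, per the labels' protocols. The deposited values are probe set intensities that the authors computed with MAS5, per the submitters' processing notes. The MAS5 version, its scaling target and any later step are not given in the sources used here. The values are linear signals with a minimum of exactly 10 on each array, the floor at which 5.43 to 12.04 percent of the values of an array lie, with array medians of 64.7 to 107.6 and maxima of 9660 to 14691.

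The 2 percent trimmed means of the arrays ranged from 224.7 to 355.3, a 1.581-fold range. By a rule set before the data were examined (a range above 1.2-fold), the arrays were therefore quantile normalized, and the values as deposited became the alternative. Signals were transformed as log2(signal + 16). Of 22626 probe sets without the array's control probe sets, 20380 have 1 gene symbol, 691 have several and 1555 have none; no symbol needed updating against the reference annotation. Probe sets were kept when at least 2 of the 64 arrays were at or above the median of their array, which kept 15337, of them 14014 with 1 symbol. Each of 9352 genes was represented by its kept probe set with the highest mean, a choice among several for 3140 genes. Probe sets with several symbols or none were left out of the comparisons. Replicate arrays correlated at 0.9473 to 0.9914 across probe sets, which are not independent replicates.

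Differences were tested with limma 3.58.1 in R 4.3.3. A single linear model with 1 coefficient for each of the 32 groups was fitted to all 64 arrays (32 residual degrees of freedom), with moderated variances following the mean signal, and contrasts gave the comparisons. For inner ear against surrounding tissue, each stage was the mean of its tissues and the stages of a window were averaged with equal weight; the value over all ages is the mean of the 3 windows. Trends are the least-squares slope over the group means multiplied by the days spanned. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05 and a change of at least 1 log2. They measure the spread between pools of different litters. Gene lists were tested with limma's camera on the same model with a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a comparison, and again with an estimated correlation. A list needed 5 measured members. In the report a p-value in brackets after a list count is this camera adjusted p. List calls printed without a second p-value also hold with an estimated correlation.

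The 28 lists cover otic regulators, hair cells, prosensory and Notch genes, membranes and otoconia, ventral and dorsal otocyst, ganglion neurons, periotic mesenchyme, cartilage, endothelium, red blood cells, macrophages, neural crest, hindbrain, skeletal muscle, epidermis, epithelium, cell cycle and cell cycle exit, early embryonic genes, ion transport, retinoic acid, BMP and TGF-beta, Wnt, FGF, Hox, glycolysis and hypoxia, and immediate early and heat shock genes. Some genes are in more than 1 list, and several markers of other cell types, such as Sox10, Col9a1 and Isl1, are also made by otic epithelium or its neurons. The genes named are the 6 with the largest positive and the 6 with the largest negative change among passing genes with the same direction at each stage of the comparison (for a trend, earlier against later stages), up to 4 members with the largest change of each list described, and a fixed panel of inner ear genes. The lists, this rule, the comparisons and the main alternatives were fixed with the rule on scaling.

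Alternatives were pseudocounts of 1 and 64, no filter and a filter of 16 arrays, values as deposited, every probe set tested alone, array weights, only the groups of a comparison, a term for the replicate number, and leaving out each array in turn, in which case the remaining array of a group is assumed to vary like the other groups. Added after the values were seen were fits without the E14 or the E11 arrays, a term for 10 arrays with high Fem1b, and fits within a dispase time. Where E9 to E10.5 and E11 to E15 are joined in a comparison, values within a dispase time are given for the leading genes and for the calls that change there. Whether equal replicate numbers pair the arrays of a stage is not given in the sources used here. In the cochlea and the utricle with ampullae, deviations of equally numbered arrays correlated across genes at 0.20 to 0.51 at all 6 stages. By a threshold of 0.1 at every stage the numbers were taken to pair those samples, and the value with a block is given where it changes a call. Such correlations do not tell shared litters from shared handling. At E14 and E15 high Fem1b lies on the same replicate number in both tissues.

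The fit, the threshold and the list test were run on simulated log2 values with the same layout, in which 200 of 9352 genes were changed by 1.5, 2 or 3 log2. Normalization, pseudocount, floor, filter and choice of probe set were not part of that test. Each simulated gene had the same spread in all groups, whereas the replicate SD of the real groups ranged from 0.155 to 0.389. The simulated changes followed the tested contrast exactly. Recovered were 94, 100 and 98.5 percent of the genes of each size for E10 against E9, 94, 100 and 100 percent for the difference in trend, and 100 percent at each size for the cochlea trend, the cochlea against the vestibular organ and the inner ear against surrounding tissue over all ages, from 67, 67 and 66 genes. Unchanged genes called numbered 5, 2, 0, 1 and 0 in that order. A shifted epithelium list was called in each of the 5 and no other list was. The simulated genes varied independently, so list calls under correlation between genes were not tested. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.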

Results

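Inner ear epithelium of CBA/J mouse embryos was profiled in 58 arrays from E9 to E15, with 6 arrays of the tissue around it (non-inner ear tissue) for comparison. Whole inner ears cover E9 to E10, the cochlea covers E10.5 to E15, the vestibular organ covers E10.5 to E12, and the utricle with the 3 ampullae and the saccule cover E12.5 to E15. Each of the 32 groups has 2 arrays, each from a separate pool of tissues, with the duplicates taken from different litters. The labels give 6 to 17 tissues per pool but no number for the 4 pooled non-inner ear arrays of E9.5 and later, and the series text gives 4 to 17. With 2 arrays per group the precision of any single stage is limited, so the spread was estimated over all 64 arrays together and most values below pool several stages. Changes are log2 differences with their standard error (SE), and a gene is called higher, lower, risen or fallen only with a limma adjusted p below 0.05 and a change of at least 1 log2. For each trend the change is the fitted line over all stages of the tissue, first stage to last. In every gene list described, the counts of risen and fallen members adjusted over the list alone were equal to the counts over all 9352 genes.

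At E9 the otic placode differed from its surroundings in 555 genes, 253 higher and 302 lower (2 arrays against 2). The keratin gene Krt23 was the highest (log2 5.79, SE 0.25), followed by Rgcc (4.10, SE 0.18) and Cnmd (4.04, SE 0.16). Wfdc2 (3.53, SE 0.19), Otog (3.39, SE 0.20), which encodes a protein of the acellular membranes of the ear, and Col9a3 (3.24, SE 0.17) came next. Lowest were the complement gene Cfb (-4.18, SE 0.51), Fitm1 (-3.37, SE 1.01), Hoxb3 (-3.32, SE 0.25), the hindbrain transcription factor genes Zic5 (-3.27, SE 0.53) and Zic1 (-3.06, SE 0.63), and Zeb2 (-3.02, SE 0.28). Gata3, an otic transcription factor gene, was higher by 2.26 (SE 0.28). Cnmd is listed at the floor of 10 on both arrays of the surrounding tissue and Fitm1 on both placode arrays, so those changes are lower bounds.

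Of 20 measured epithelial genes, 16 were higher in the E9 placode and 4 did not pass (camera adjusted p = 9.01e-20), among them Ap1m2 (2.94, SE 0.21), Esrp1 (2.85, SE 0.20) and Epcam (2.58, SE 0.18). Endothelial genes were lower in 5 of 11, with none higher (7.43e-08): Pecam1 (-2.17, SE 0.30) and Sox17 (-2.07, SE 0.29). Hindbrain markers were lower in 6 of 11, with none higher (1.67e-07), as for Fabp7 (-2.90, SE 0.59) and Hoxb1 (-2.57, SE 0.23). Hox genes were lower in 5 of 13, with none higher (2.53e-07), including Hoxc4 (-2.51, SE 0.24), at the floor of 10 on both placode arrays and so a lower bound. Periotic mesenchyme genes were lower in 8 of 22 and higher in none (2.04e-05; adjusted p = 0.0880 with an estimated correlation), Twist1 (-2.19, SE 0.31) and Lum (-1.79, SE 0.38) the most. With the values as deposited the median of all genes was 0.32 here, against -0.05, with 863 higher and 124 lower (87.4 percent higher against 45.6). Fitm1 did not pass without any 1 of the 4 arrays (adjusted p 0.0618 to 0.0812), and Sox17 changed by only -0.24 without the low-value filter, where another probe set represents it. The Hox list was no longer called when 16 arrays had to reach the array median (adjusted p = 0.4039).

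**Figure D1:**
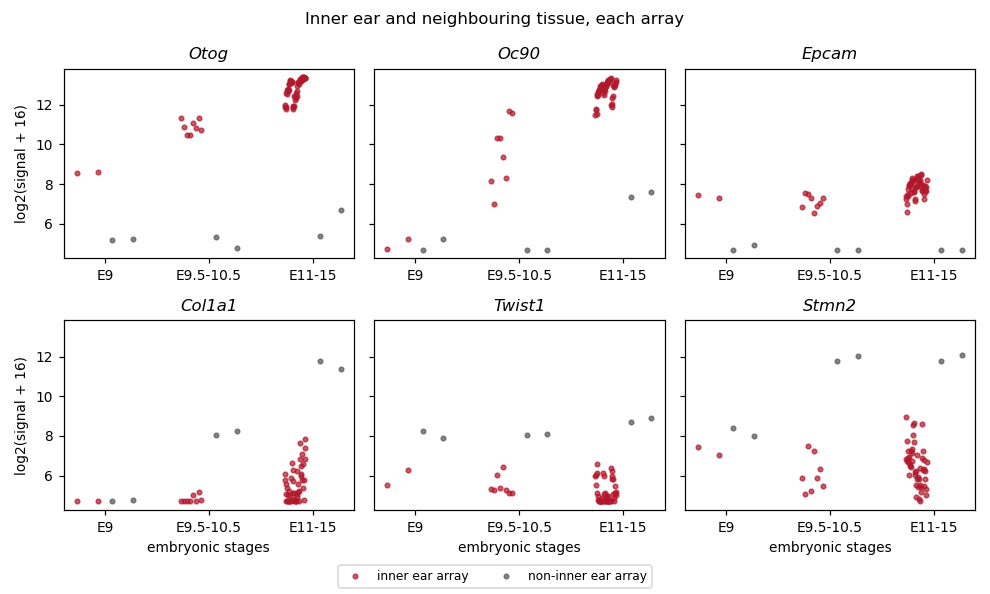
Signal of 6 genes on the log2(signal + 16) scale (vertical axis) at E9, E9.5 to E10.5 and E11 to E15 (horizontal axis), each point 1 array, inner ear in red and non-inner ear tissue in grey. Otog stands higher in the inner ear by 3.39, 5.80 and 6.72 log2 at E9, E9.5 to E10.5 and E11 to E15, and Stmn2 lower by -5.87 and -5.38 in the later pair of stage windows.

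From E9.5 to E10.5 the inner ear differed from surrounding tissue in 786 genes, 348 higher and 438 lower (8 arrays against 2). Structural genes of the inner ear led the higher group: Otog (5.80, SE 0.16), Col9a3 (5.15, SE 0.14) and Oc90 (4.69, SE 0.19), the gene of the main otoconial protein. Krt23 (4.05, SE 0.20), Ap1m2 (3.97, SE 0.17) and Erbb3 (3.94, SE 0.13) followed. The lowest genes were neuronal or neural: Stmn2 (-5.87, SE 0.53), the proneural gene Neurog2 (-5.26, SE 0.27), Stmn4 (-4.81, SE 0.48), Fabp7 (-4.67, SE 0.47), the neurofilament gene Nefl (-4.61, SE 0.30) and Fez1 (-4.55, SE 0.25). Col9a3 and Oc90 are listed at the floor of 10 on both arrays of the surrounding tissue, so their changes are lower bounds.

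Epithelial genes again stood higher at E9.5 to E10.5 in 16 of 20, with 4 not passed (5.02e-23), as for St14 (3.79, SE 0.17) and Prss8 (3.70, SE 0.22). Of 23 otic regulators 6 were higher and none lower (6.24e-05), with Tbx3 at 2.01 (SE 0.17), and of 15 genes of the ear's membranes and otoconia 6 were higher and 1, Sparcl1 (-2.35, SE 0.15), was lower (7.72e-07). Ganglion neuron genes were lower in 9 of 21 and higher in none (1.33e-05), including Ina (-3.78, SE 0.29) and Gap43 (-3.34, SE 0.27). Hox genes were lower in 7 of 13 (3.66e-09), with Hoxb3 at -4.53 (SE 0.20) and Hoxb1 at -4.22 (SE 0.19). Periotic mesenchyme genes were lower in 11 of 22 (6.15e-08), among them Col1a1 (-3.38, SE 0.36), Twist1 (-2.57, SE 0.25) and Pdgfra (-2.57, SE 0.26). Red blood cell genes were lower in 3 of 8 (0.0141; adjusted p = 0.0578 with an estimated correlation), led by the embryonic globin genes Hba-x (-2.65, SE 0.35) and Hbb-bh1 (-2.26, SE 0.33). As deposited, the median of all genes stood at 0.33 against 0.01 and the split became 736 higher and 255 lower (74.3 percent higher against 44.3), and Col1a1 changed by only -0.93, where another probe set represents it. The Hox list was not called with the filter of 16 arrays (adjusted p = 0.2274), and the red blood cell list not without replicate 1 of the surrounding tissue (adjusted p = 0.0503).

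Across E11 to E15 the inner ear differed from surrounding tissue in 1460 genes, 792 higher and 668 lower (48 arrays against 2). The counts of the stage windows rest on unlike numbers of arrays, and a change between windows was not tested. Otog (6.72, SE 0.14), Oc90 (5.22, SE 0.17), the glycine-cleavage gene Gldc (4.97, SE 0.15), Sox21 (4.92, SE 0.23), Fbxo2 (4.86, SE 0.20) and Dtna (4.78, SE 0.34) were the highest in the inner ear. The collagen gene Col1a1 (-6.05, SE 0.32), Stmn2 (-5.38, SE 0.48), 1700120B22Rik (-4.90, SE 0.28), Gap43 (-4.72, SE 0.25), the protease gene Htra1 (-4.67, SE 0.25) and the cartilage matrix gene Matn4 (-4.64, SE 0.32) were the lowest. 1700120B22Rik is at the floor of 10 on 36 of the 48 inner ear arrays and Col1a1 on 12. Gata3 was higher by 1.45 (SE 0.20) and Sox10 by 2.29 (SE 0.19).

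In this late window 20 of 22 periotic mesenchyme genes were lower (1.51e-14), including Col1a2 (-3.81, SE 0.16), Twist1 (-3.62, SE 0.22) and Snai2 (-3.55, SE 0.21), and 15 of 20 epithelial genes were higher (2.95e-14), including Cldn7 (4.57, SE 0.16), Prss8 (4.53, SE 0.20) and Ap1m2 (4.42, SE 0.15). Cartilage genes were lower in 5 of 12 (7.05e-06), with Matn1 at -4.51 (SE 0.16) and Hapln1 at -4.50 (SE 0.21). Ganglion neuron genes were lower in 10 of 21 and higher in 2 (0.0015), with Ina at -4.28 (SE 0.26) and Nefl at -3.46 (SE 0.27). Otic regulators were higher in 9 of 23 (0.0016), among them Sox2 (3.10, SE 0.11), Tbx3 (2.48, SE 0.15) and Otx2 (2.43, SE 0.17). Prosensory and Notch genes went both ways, 6 higher and 4 lower of 24 (0.0249). Examples are Hey1 (2.46, SE 0.12) and Hey2 (2.17, SE 0.20) against Notch2 (-2.49, SE 0.30). Hair cell genes were higher in 7 of 20 and lower in 1, and the list was not called (0.1515). Espn (2.69, SE 0.41) and Gfi1 (1.83, SE 0.16) are at the floor of 10 on both arrays of surrounding tissue, so these are lower bounds. Ush1c was higher by 2.56 (SE 0.21). As deposited, the median over all genes was 0.13 against -0.01, and the split was 1056 higher and 495 lower (68.1 percent higher against 54.2).

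Averaged over the 3 stage windows (58 arrays against 6), 230 genes were higher in the inner ear and 313 lower. The highest of those with the same direction at every stage were Otog (5.30, SE 0.10), Krt23 (4.02, SE 0.12), Ap1m2 (3.78, SE 0.10), the neuregulin receptor gene Erbb3 (3.43, SE 0.08), the splicing factor gene Esrp1 (3.33, SE 0.10) and Wfdc2 (3.32, SE 0.10). The lowest were Stmn2 (-4.07, SE 0.33), Zic5 (-3.94, SE 0.26), Fez1 (-3.62, SE 0.15), Fabp7 (-3.57, SE 0.29), Stmn4 (-3.53, SE 0.29) and the macrophage gene Mrc1 (-3.46, SE 0.23). Gata3 (1.73, SE 0.14), Sox10 (1.52, SE 0.13), Epcam (2.71, SE 0.09) and Oc90 (3.30, SE 0.11) were higher too, although at E9 Oc90 (0.01, SE 0.23) and Sox10 (0.60, SE 0.26) did not pass. Epithelial genes were higher in 15 of 20 (3.97e-20), with St14 at 3.31 (SE 0.10) and Cldn7 at 3.29 (SE 0.11). Periotic mesenchyme genes were lower in 12 of 22 (5.44e-14), with Col1a1 at -3.16 (SE 0.22) and Twist1 at -2.79 (SE 0.15). Of 8 macrophage genes only Mrc1 was lower (0.0173; adjusted p = 0.1188 with an estimated correlation), while Cx3cr1 (-0.61) and Cd14 (-0.57) did not pass. On the deposited scale the median of all genes was 0.27 against -0.01, with 480 higher and 205 lower (70.1 percent higher against 42.4).

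Between the otic placode at E9 and the otic vesicle at E10, 349 genes rose and 146 fell (2 arrays against 2). Oc90 rose the most (5.37, SE 0.23), then Cfb (4.35, SE 0.51), the neuronal differentiation gene Neurod1 (3.85, SE 0.22), Fitm1 (3.44, SE 1.01), Espn (3.13, SE 0.56), whose product bundles actin in stereocilia, and Pde9a (2.90, SE 0.23). The glucose transporter gene Slc2a3 fell the most (-4.24, SE 0.41), then Tfap2c (-3.37, SE 0.40), Hapln1 (-2.56, SE 0.29), Plcg1 (-2.45, SE 0.31), Mogat2 (-2.28, SE 0.29) and Slc15a2 (-2.20, SE 0.23). Fitm1 and Pde9a are listed at the floor of 10 on both E9 arrays and Plcg1 on both E10 arrays, so those changes are lower bounds.

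Among 15 genes of membranes and otoconia 5 rose from E9 to E10 and none fell (0.00054; adjusted p = 0.0934 with an estimated correlation): Otog (1.88, SE 0.20), Col11a1 (1.71, SE 0.21) and Col9a3 (1.66, SE 0.17) beside Oc90. Glycolysis and hypoxia genes fell in 3 of 16 (0.0103; adjusted p = 0.1447 with an estimated correlation), which besides Slc2a3 are Slc2a1 (-1.39, SE 0.24) and Bnip3 (-1.22, SE 0.22). Genes of cell cycle exit rose in 5 of 13 without a list call (0.0572), as Btg2 (2.82, SE 0.29), Gadd45g (2.65, SE 0.24) and Cdkn1a (2.16, SE 0.35) did. Otic regulators rose in 4 of 23, with the median of the list near 0, its mean at 0.42 and no list call (0.3208). Tbx3 (2.78, SE 0.21) and Tbx1 (1.57, SE 0.33) were among the 4. Fitm1 did not pass without either E9 array or without replicate 1 of E10 (adjusted p 0.0600 to 0.0642).

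**Figure D2:**
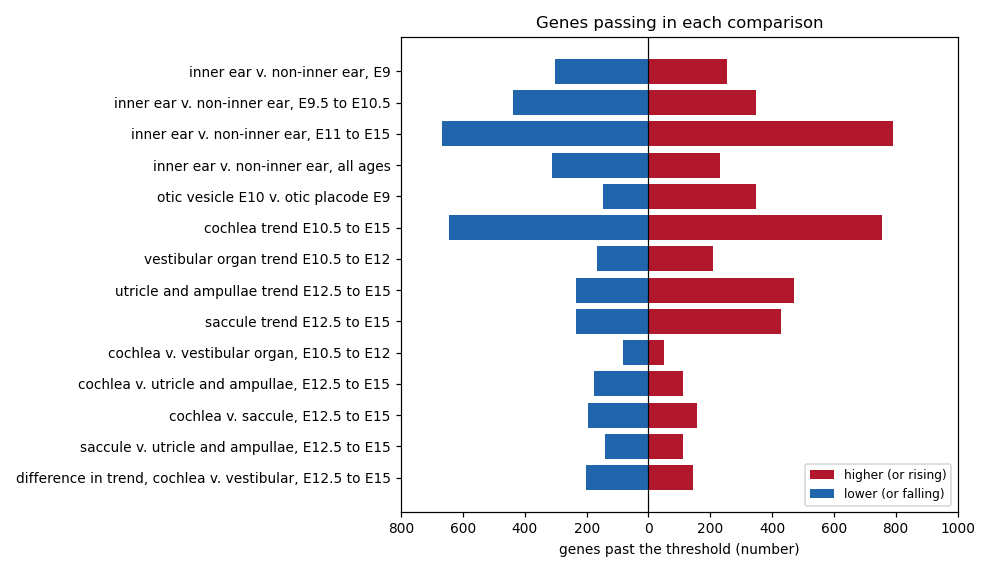
Genes called higher or risen and lower or fallen (horizontal axis, number of genes) in each of the 14 comparisons (vertical axis), each bar 1 direction. The inner ear against its surroundings at E11 to E15 has 792 and 668, the cochlea trend 754 and 644, and the cochlea against the vestibular organ 50 and 82.

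Over E10.5 to E15 the cochlea changed in 1398 genes, 754 rising and 644 falling (20 arrays, 10 stages). The tectorial membrane genes Tecta (8.20, SE 0.15) and Tectb (6.84, SE 0.24) were among those that rose the most. Others were the small heat shock protein gene Cryab (7.49, SE 0.19), Mia (7.09, SE 0.20), Smoc2 (6.11, SE 0.16) and Agr3 (6.05, SE 0.18). The embryonic globin genes Hbb-y (-6.41, SE 0.35), Hbb-bh1 (-6.16, SE 0.29) and Hba-x (-4.01, SE 0.31) fell. So did Lin28a (-5.96, SE 0.19), an RNA-binding protein gene of early embryonic cells, Neurod1 (-5.10, SE 0.16) and the phosphatase gene Dusp9 (-4.46, SE 0.15). The cell cycle inhibitor gene Cdkn1b rose by 2.13 (SE 0.27), Gata3 by 1.70 (SE 0.20) and Atoh1, the hair cell transcription factor gene, by 1.80 (SE 0.13), while the proliferation marker gene Mki67 fell by 1.39 (SE 0.15).

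Cell cycle genes fell in 31 of 36 in the cochlea, with none risen (7.85e-23), Rrm2 (-3.02, SE 0.27), Ube2c (-2.91, SE 0.17) and Cenpa (-2.69, SE 0.13) the most. Membrane and otoconia genes rose in 12 of 15 (2.94e-12), with Epyc at 4.49 (SE 0.16) and Sparcl1 at 4.07 (SE 0.13) after the tectorins. Ion transport genes rose in 7 of 17 (8.07e-05), including the water channel gene Aqp5 (4.80, SE 0.24), the gap junction gene Gjb2 (4.21, SE 0.18) and the anion exchanger gene Slc26a4 (3.77, SE 0.16). Wnt pathway genes rose in 11 of 24 and fell in 1 (0.0018), with Wnt7a at 5.08 (SE 0.28) and Dkk2 at 4.74 (SE 0.33). Hair cell genes split, 4 risen and 2 fallen of 20 (0.3413): Ush1c (2.41, SE 0.20), Smpx (2.24, SE 0.20) and Myo6 (1.92, SE 0.19) rose and Myo7a (-2.31, SE 0.20) fell. Ganglion neuron genes fell in 7 of 21 and rose in 1 (0.3799), the median of the list at 0.13, its mean at -0.47 and its test downward, with Nefm at -2.16 (SE 0.45) and Elavl4 at -1.73 (SE 0.26). Red blood cell genes had 3 fallen, the globins, and 1 risen of 8 (0.1662), Slc4a1 (1.61, SE 0.10), of which another probe set fell.

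Tissue of E9 to E10.5 stood 8 to 10 minutes in dispase and that of E11 to E15 20 to 25 minutes, so stage and incubation cannot be separated across that boundary. Over E11 to E15 alone the cochlea trend had 1358 genes, 717 risen and 641 fallen, with Tecta at 7.62, Cryab at 7.62, Tectb at 6.56, Mia at 6.31, Agr3 at 5.51, Wnt7a at 4.74, Smoc2 at 4.72, Lin28a at -4.38, Neurod1 at -4.18, Dusp9 at -3.98, Hbb-y at -6.51, Hbb-bh1 at -5.62 and Hba-x at -3.67. The E14 arrays are part of this trend. On them 141 genes, Hbb-y (-1.95) among them, lie more than 1 log2 below the mean of E13.5 and E14.5 in at least 2 of the 3 late tissues, and 41 lie above. So are the E11 arrays, with 116 genes below and 14 above in the cochlea and the vestibular organ alike; these 4 arrays have 9.81 to 12.04 percent of their values at the floor, against at most 8.63 on any other array. Without E14 the count was 1320 and without E11 1478. The fit without E11 joins both dispase times and the fit over E11 to E15 keeps the E11 arrays, so neither is free of both limits. As deposited, the median of all genes was 0.24 against 0.06, with 987 risen and 493 fallen (66.7 percent risen against 53.9). Deposited maxima of the cochlea arrays were 9660 to 10969 at E10.5 to E12 and 13291 to 14691 from E12.5. The log2 signal of Lnx2 fell at the same point, from 7.96 and 8.37 at E12 to 5.86 and 5.94 at E12.5. A processing difference at that break cannot be separated from stage. Cryab rose by only 0.42 at a pseudocount of 1, where another probe set represents it, and Atoh1 by 0.97 at a pseudocount of 64.

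In the vestibular organ from E10.5 to E12, 209 genes rose and 167 fell (8 arrays, 4 stages). The adult globin gene Hbb-b2 (3.68, SE 0.75), Smoc2 (3.55, SE 0.21), Tmem267 (3.28, SE 0.26), the protocadherin gene Pcdh20 (3.24, SE 0.26), Kirrel (3.22, SE 0.50) and Agr3 (3.22, SE 0.24) rose the most. Lin28a fell the most (-4.68, SE 0.26), then Igdcc3 (-4.31, SE 0.34), the tubulin gene Tubb6 (-3.63, SE 0.22), Taar1 (-3.15, SE 0.47), B4galnt2 (-3.07, SE 0.26) and 1700120B22Rik (-2.96, SE 0.37). Otx2 rose by 2.50 (SE 0.22) and Oc90 by 1.22 (SE 0.22), and Neurod1 fell (-1.26, SE 0.21).

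Membrane and otoconia genes rose in 6 of 15 in the vestibular organ (0.0025; adjusted p = 0.2369 with an estimated correlation), Slc26a4 (1.64, SE 0.21), Tecta (1.38, SE 0.20) and Otog (1.27, SE 0.19) the most. Of 36 cell cycle genes 2 fell, Bub1 (-1.24, SE 0.22) and Mcm5 (-1.07, SE 0.21), and the list was called (0.0096; adjusted p = 0.5143 with an estimated correlation). Early embryonic genes besides Lin28a had Igf2bp1 fallen (-1.58, SE 0.22) and Dnmt3a risen (1.67, SE 0.17), 3 down and 1 up of 11 (0.0777). In the retinoic acid list the synthesis gene Aldh1a3 rose (2.85, SE 0.24) and Aldh1a1 (-1.91, SE 0.25) and the binding protein gene Crabp1 (-1.83, SE 0.41) fell, 1 up and 3 down of 10 (0.9381), with a median of 0.06, a mean of -0.04 and an upward test. Over E11 to E12 alone, with the longer incubation throughout, 238 genes passed, 158 risen and 80 fallen. Smoc2 (2.52), Agr3 (2.64), Igdcc3 (-3.84), Lin28a (-2.86), Tubb6 (-2.03), Otx2 (1.13) and Neurod1 (-1.27) passed there. So did Slc26a4 (1.78), Kirrel (1.74), Aldh1a3 (1.18), Pcdh20 (1.16), Taar1 (-1.65), B4galnt2 (-1.61) and Aldh1a1 (-1.15). Hbb-b2 (2.16), Tmem267 (0.37), 1700120B22Rik (-0.46), Tecta (0.87), Otog (0.58), Oc90 (0.39), Bub1 (-0.68), Mcm5 (-0.81), Igf2bp1 (-0.86) and Dnmt3a (0.73) did not, nor did Crabp2 (-0.92), the other fallen gene of the retinoic acid list, and the membrane and otoconia list was not called there (adjusted p = 0.1550). The E11 arrays stand apart here too, and without them the trend had 406 genes and the cell cycle list was not called (adjusted p = 0.0700). That fit joins both dispase times, while the fit over E11 to E12 begins with the E11 arrays, so neither is free of both limits. Tecta rose by only 0.76 at a pseudocount of 64, and the membrane and otoconia list was not called with only the groups of the comparison (adjusted p = 0.0640). As deposited, the median trend of all genes was 0.12 against 0.01, with 300 risen and 124 fallen (70.8 percent risen against 55.6).

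In the utricle with ampullae from E12.5 to E15, 471 genes rose and 233 fell (12 arrays, 6 stages). Smpx (5.42, SE 0.25), Matn4 (5.27, SE 0.37), Cars (5.27, SE 0.22), the calmodulin-like gene Calml4 (4.84, SE 0.22), Otor (4.68, SE 0.48) and the hair cell transcription factor gene Gfi1 (4.65, SE 0.18) rose the most. Hbb-y fell the most (-5.87, SE 0.42), then Stmn4 (-3.13, SE 0.51), the retinoic acid binding protein gene Crabp1 (-2.83, SE 0.36), Hmga2 (-2.67, SE 0.25), Nr2f1 (-2.60, SE 0.30) and S1pr3 (-2.49, SE 0.84). Atoh1 rose by 2.20 (SE 0.16), and Mki67 (-1.38, SE 0.18) and Neurod1 (-1.83, SE 0.19) fell.

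Of 20 hair cell genes 10 rose in the utricle with ampullae and none fell (4.41e-11), with Myo6 at 3.46 (SE 0.22) and Pcp4 at 2.86 (SE 0.27). Cell cycle genes fell in 19 of 36 (2.6e-21), Rrm2 (-2.26, SE 0.33), Uhrf1 (-1.81, SE 0.13) and Bub1 (-1.76, SE 0.20) the most. Membrane and otoconia genes rose in 10 of 15 (2.98e-10), such as Sparcl1 (4.58, SE 0.16) and Tecta (2.72, SE 0.18), and ion transport genes in 4 of 17 (5.8e-05), led by the nuclear receptor gene Esrrb (4.29, SE 0.27). The other risen ion transport genes, Aqp1 (0.57), Aqp5 (0.96) and Car12 (just short of 1 log2), did not pass at a pseudocount of 64. Aqp1 also fell below 1 log2 without some single arrays (0.85 to 0.99). Early embryonic genes fell in 4 of 11 (0.000608), with Igf2bp1 at -1.52 (SE 0.20) after Hmga2. Glycolysis and hypoxia genes fell in 2 of 16 (0.000145), the glucose transporter genes Slc2a1 (-1.22, SE 0.20) and Slc2a3 (-1.07, SE 0.34). The E14 arrays lie in this trend, with Hbb-y among the genes lower on them, and without them 691 genes passed and Slc2a3 (-0.98) did not. Without replicate 1 of E12.5 Slc2a1 fell just short of 1 log2, and Slc2a3 did not pass without that array (-1.06) or without replicate 1 of E13 (-0.98) or of E15 (-0.97). With a term for 10 arrays with a high Fem1b signal (-0.97) and at a pseudocount of 64 (-0.62) Slc2a3 did not pass either. S1pr3 was lost without each of 5 arrays (adjusted p 0.0521 to 0.1598) and with only the groups of the comparison (0.0527), and Cars rose by only 0.32 at a pseudocount of 1, where another probe set represents it.

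In the saccule from E12.5 to E15, 429 genes rose and 233 fell (12 arrays, 6 stages). Smpx rose the most here too (6.12, SE 0.25), followed by the cytokine gene Il33 (5.50, SE 0.19), Ap3b2 (5.38, SE 0.36), the ciliary gene Spag6l (5.21, SE 0.23), Ttr (4.86, SE 1.06) and Tectb (4.79, SE 0.29). The lowest were Hbb-y (-6.01, SE 0.42), the placental growth factor gene Pgf (-3.73, SE 0.33), Hba-x (-3.32, SE 0.37), Hmga2 (-3.01, SE 0.25), Crabp1 (-2.81, SE 0.36) and Neurod1 (-2.75, SE 0.19). Atoh1 (2.00, SE 0.16), Pou4f3 (1.41, SE 0.24) and Myo7a (2.32, SE 0.24) rose, and Mki67 fell (-1.25, SE 0.18).

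Hair cell genes rose in 13 of 20 in the saccule and fell in none (1.62e-16), including Gfi1 (4.38, SE 0.18), Myo6 (3.54, SE 0.22) and Espn (3.04, SE 0.47). Cell cycle genes fell in 21 of 36 (2.25e-22), Rrm2 (-2.29, SE 0.33), Cenpa (-2.01, SE 0.16) and Birc5 (-1.92, SE 0.15) the most. Membrane and otoconia genes rose in 6 of 15 (2.65e-10), with Sparcl1 at 3.75 (SE 0.16), Tecta at 3.61 (SE 0.18) and Slc26a4 at 2.23 (SE 0.19). Early embryonic genes fell in 3 of 11 (0.0018), Igf2bp1 (-2.08, SE 0.20) and Mycn (-1.55, SE 0.15) after Hmga2, while Lin28a (-0.66) did not pass. Wnt pathway genes rose in 5 of 24 (0.0038), with Wnt7a at 2.89 (SE 0.33), Dkk3 at 2.39 (SE 0.22) and Dkk2 at 2.05 (SE 0.40). The E14 arrays lie in this trend as well, again with lower Hbb-y, and without them 657 genes passed.

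**Figure D3:**
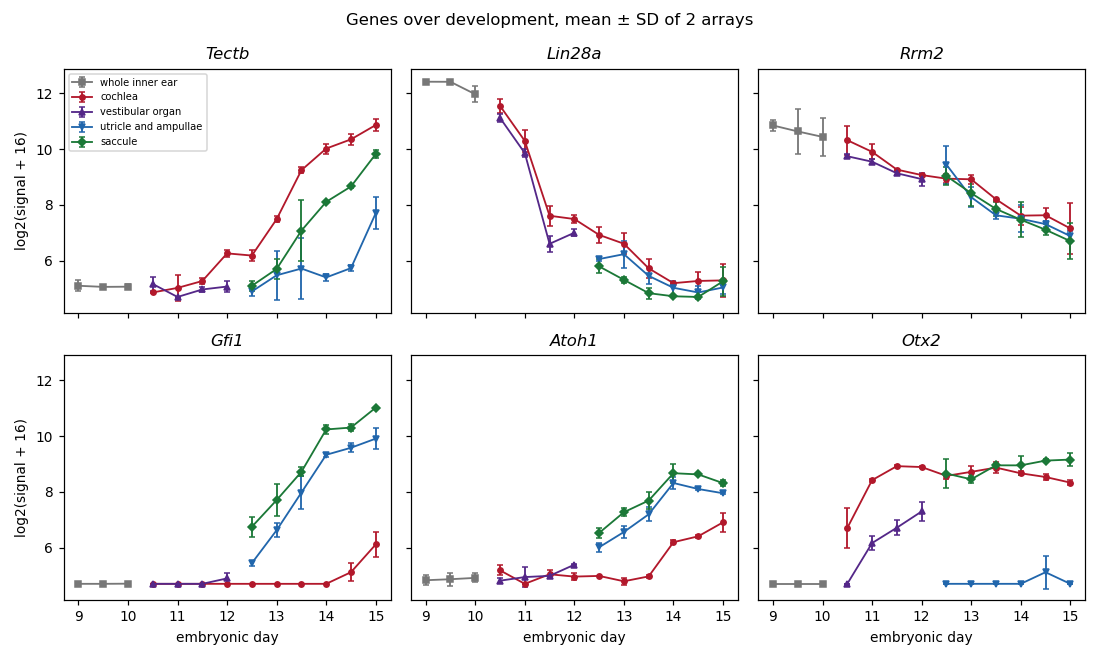
Mean signal of 6 genes on the log2(signal + 16) scale (vertical axis) against embryonic day (horizontal axis) in each inner ear tissue, each point the mean of 2 arrays with a bar of 1 standard deviation. Gfi1 climbs by 4.65 log2 in the utricle with ampullae and 4.38 in the saccule over E12.5 to E15, and Lin28a falls by -5.96 in the cochlea over E10.5 to E15.

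Between E10.5 and E12 the cochlea and the vestibular organ differed in 132 genes, 50 higher and 82 lower in the cochlea (8 arrays against 8). Higher in the cochlea were Clu (3.02, SE 0.19), the Notch target gene Hey2 (2.56, SE 0.14), the activin antagonist gene Fst (2.46, SE 0.12), Muc15 (2.45, SE 0.13), the Wnt antagonist gene Frzb (2.39, SE 0.17) and the neuropeptide gene Tac1 (2.28, SE 0.11). Lower were the homeobox gene Dlx1 (-3.17, SE 0.29), Col14a1 (-3.09, SE 0.22), Apobec2 (-3.04, SE 0.20), the potassium channel gene Kcnd2 (-2.70, SE 0.17), Vnn1 (-2.39, SE 0.15) and Pcdh20 (-2.37, SE 0.14), with Oc90 at -1.31 (SE 0.12).

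Of 12 ventral otocyst genes 4 were higher in the early cochlea and none lower (1.18e-08), Otx2 (2.01, SE 0.12) and Gata3 (1.36, SE 0.14) among them beside Fst. Of 20 dorsal otocyst genes 5 were lower and none higher (6.81e-05), Meis2 (-1.78, SE 0.09) and Hmx2 (-1.56, SE 0.14) the most, of which Hmx2 (-0.78) did not pass at a pseudocount of 64, nor did Meis1 (-0.74). Retinoic acid genes were lower in 5 of 10 and higher in 1 (0.000343): the synthesis genes Aldh1a2 (-2.24, SE 0.24) and Aldh1a3 (-1.90, SE 0.13) were lower and the degradation gene Cyp26a1 (1.47, SE 0.17) was higher. Periotic mesenchyme genes were higher in 2 of 22 (0.0051; adjusted p = 0.3358 with an estimated correlation), Postn (1.18, SE 0.13) and Dcn (1.08, SE 0.13), of which neither passed at a pseudocount of 64 (0.76 and 0.96), and the list was not called with only the groups of the comparison (adjusted p = 0.0510). Dcn also did not pass without replicate 1 of the E10.5 cochlea (0.96). Epithelial genes were lower in 2 of 20 (0.0444; adjusted p = 0.6215 with an estimated correlation), Cldn4 (-1.48, SE 0.17) and Krt7 (-1.13, SE 0.13; -0.70 at a pseudocount of 64). That list was not called at a pseudocount of 1 (adjusted p = 0.0502), as deposited (0.2218) or without each of 6 single arrays (0.0529 to 0.0930).

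At E10.5 alone, with the shorter incubation, the cochlea and vestibular organ differed in 232 genes (60 higher, 172 lower), and at E11 to E12 in 135 (64 higher, 71 lower). Values at E10.5 and at E11 to E12 passed in each for Hey2 (1.76 and 2.83), Muc15 (1.69 and 2.71), Frzb (1.28 and 2.76), Otx2 (2.00 and 2.02), Cyp26a1 (1.59 and 1.43), Dlx1 (-3.18 and -3.16), Kcnd2 (-2.62 and -2.73), Col14a1 (-3.22 and -3.05), Apobec2 (-2.30 and -3.29), Vnn1 (-2.53 and -2.35), Cldn4 (-1.26 and -1.55), Hmx2 (-1.32 and -1.64), Aldh1a2 (-2.49 and -2.15) and Meis2 (-1.14 and -1.99). Genes that passed only at E11 to E12 were Clu (0.79 and 3.77), Fst (0.53 and 3.11), Tac1 (0.07 and 3.02), Gata3 (0.58 and 1.62), Aldh1a3 (-0.92 and -2.23), Pcdh20 (-0.91 and -2.85), Krt7 (-0.60 and -1.31), Postn (0.73 and 1.33), Dcn (0.23 and 1.37) and the dorsal otocyst genes Meis1 (-0.79 and -1.37) and Tbx1 (-0.74 and -1.23). Oc90 (-2.79 and -0.82) and Tjp3 (-1.17 and -0.34) passed only at E10.5. The periotic mesenchyme list was not called at E10.5 (adjusted p = 0.5230), and the epithelium list in neither (0.0526 and 0.0829). The difference between those stages was not tested. On the deposited scale the median of all genes in this comparison was -0.28 against -0.01, with 24 higher and 194 lower (11.0 percent higher against 37.9), and there Cyp26a1 (0.94) and Dcn (0.90) did not pass. Deposited trimmed means at E10.5 to E12 were 233.8 to 258.6 on the cochlea arrays and 296.1 to 322.5 on the vestibular organ arrays. Array maxima were 9660 to 10969 and 13192 to 14229. Quantile normalization evens out this scale, but a processing difference behind it cannot be separated from tissue. The E11 arrays stand apart in both tissues, and without them 145 genes passed.

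The late cochlea (E12.5 to E15) differed from the utricle with ampullae in 287 genes, 112 higher and 175 lower in the cochlea (12 arrays against 12). Higher were Tac1 (4.57, SE 0.09), Clu (4.46, SE 0.15), the homeobox gene Gsc (4.29, SE 0.16), Cyp26a1 (4.11, SE 0.14), Otx2 (3.84, SE 0.10), which is at the floor of 10 on 11 of the 12 utricle with ampullae arrays, and Fst (3.53, SE 0.10). Lower were Kcnd2 (-4.35, SE 0.14), Apobec2 (-4.32, SE 0.16), Gfi1 (-3.14, SE 0.09), Vit (-3.11, SE 0.08), Meis2 (-3.09, SE 0.08) and the opioid peptide gene Penk (-3.08, SE 0.12). Vit is listed at the floor of 10 on all 12 cochlea arrays, so its change is a lower bound. Hmga2 was higher by 1.96 (SE 0.12) and Tectb by 3.21 (SE 0.14).

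Ventral otocyst genes were higher in the cochlea in 7 of 12 and lower in none (1.75e-14), including the nuclear receptor gene Nr2f1 (3.39, SE 0.14) and Gata3 (3.01, SE 0.11). Hair cell genes were lower in 6 of 20 (2.93e-08), among them Pcp4 (-2.86, SE 0.13), Atoh1 (-1.65, SE 0.08) and Myo6 (-1.42, SE 0.11). Dorsal otocyst genes were lower in 4 of 20, as Hmx2 (-2.12, SE 0.11), and higher in 2, Irx3 (3.26, SE 0.14) and Irx5 (2.43, SE 0.11), with the list called lower (0.000712) but not when 16 arrays had to reach the array median (adjusted p = 0.0773). Retinoic acid genes had 3 higher and 4 lower of 10 (0.0275; adjusted p = 0.1888 with an estimated correlation, 0.0687 as deposited, 0.0566 with only the groups of the comparison, 0.1032 with the replicate number as a block). The synthesis genes Aldh1a2 (-2.95, SE 0.19), Aldh1a3 (-2.80, SE 0.11) and Aldh1a1 (-2.63, SE 0.11) were among the lower. Of 16 glycolysis and hypoxia genes only Egln3 passed (-1.42, SE 0.10), and the list was called lower (0.000712). Without the E14 arrays 266 genes passed.

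Against the saccule the late cochlea differed in 353 genes, 156 higher and 197 lower (12 arrays against 12). Cyp26a1 (4.31, SE 0.14), Tac1 (4.24, SE 0.09), the proteoglycan gene Lum (3.91, SE 0.15), Clu (3.68, SE 0.15), Fst (3.66, SE 0.10) and Gata3 (3.61, SE 0.11) were higher in the cochlea. Gfi1 (-4.12, SE 0.09), Aldh1a3 (-3.03, SE 0.11), the neurofilament gene Nefm (-2.94, SE 0.27), Fabp7 (-2.82, SE 0.24), Agr3 (-2.78, SE 0.10) and Otoa (-2.77, SE 0.12), the gene of otoancorin, were lower. Tectb was higher by 1.61 (SE 0.14), and Otx2 (-0.27, SE 0.10) did not reach 1 log2.

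Hair cell genes were lower in the cochlea than in the saccule in 8 of 20 and higher in none (3.51e-08), with Atoh1 at -2.14 (SE 0.08), Pcp4 at -1.94 (SE 0.13) and Myo6 at -1.89 (SE 0.11). BMP and TGF-beta genes were higher in 5 of 21 and lower in 1 (0.000546), among them Bmp4 (3.00, SE 0.09) and Tgfb2 (1.73, SE 0.10). Ventral otocyst genes were higher in 4 of 12 (0.000546), with Hmga2 at 2.69 (SE 0.12) and Gli2 at 1.14 (SE 0.10), and early embryonic genes in 2 of 11 (0.0049), Hmga2 and Igf2bp1 (1.15, SE 0.09). Prosensory and Notch genes were higher in 5 of 24 (0.0192), as Id2 (1.66, SE 0.09) and Hey2 (1.36, SE 0.11). Periotic mesenchyme genes went both ways, 2 higher and 5 lower of 22 (0.2097): Lum and Dcn (3.51, SE 0.10) against Col3a1 (-1.71, SE 0.11) and Postn (-1.28, SE 0.10). Without the E14 arrays 322 genes passed.

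The saccule and the utricle with ampullae differed in 254 genes at E12.5 to E15, 112 higher and 142 lower in the saccule (12 arrays against 12). Otx2 (4.11, SE 0.10, again against 11 of 12 arrays at the floor of 10), the crystallin gene Crym (3.52, SE 0.08), Otoa (3.47, SE 0.12), Gsc (3.39, SE 0.16), Postn (3.23, SE 0.10) and Wnt4 (3.20, SE 0.12) were higher in the saccule. Dlx1 (-5.49, SE 0.23), Apobec2 (-3.81, SE 0.16), the aminopeptidase gene Enpep (-3.53, SE 0.10), Aldh1a2 (-3.45, SE 0.19), Kcnd2 (-3.37, SE 0.14) and Zfp503 (-3.33, SE 0.10) were lower. Tectb was higher by 1.59 (SE 0.14).

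Dorsal otocyst genes were lower in the saccule in 5 of 20 and higher in none (2.24e-08), including Meis2 (-2.68, SE 0.08), Meis1 (-2.38, SE 0.08), Bmp4 (-2.25, SE 0.09) and Bmp2 (-1.98, SE 0.09), and BMP and TGF-beta genes in 8 of 21 (1.53e-07), with Bmp6 (-2.49, SE 0.06) the most. Membrane and otoconia genes were higher in 4 of 15 (0.0491; adjusted p = 0.3235 with an estimated correlation), with Tecta at 1.51 (SE 0.09) after Otoa and Tectb. Hair cell genes were higher in 1 of 20, Ush1c (1.24, SE 0.12), with Gfi1 (0.98) short of 1 log2 (0.0491; adjusted p = 0.3124 with an estimated correlation). Periotic mesenchyme genes were higher in 4 of 22 and lower in 2 (0.0491; adjusted p = 0.3991 with an estimated correlation), Six2 (2.25, SE 0.10) against Lum (-2.21, SE 0.15) and Dcn (-2.13, SE 0.10). Those last 3 lists were also not called at a pseudocount of 1 (adjusted p 0.0831 for hair cells, 0.0589 for membranes and otoconia, 0.0550 for periotic mesenchyme). With a term for the 10 arrays of high Fem1b none of them was called (each 0.0522), and periotic mesenchyme was not called at a pseudocount of 64 (0.0623), without the filter (0.2743) or with the filter of 16 arrays (0.6576). They were not called either without many single arrays, replicate 2 of the E14 utricle with ampullae among them (0.0872, 0.0680 and 0.0872). Without the E14 arrays 241 genes passed.

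How genes changed from E12.5 to E15 differed between the cochlea and the vestibular tissues in 348 genes, 145 with the higher and 203 with the lower trend in the cochlea (36 arrays, the vestibular trend being the mean of saccule and utricle with ampullae). Higher cochlear trends were those of Crabp1 (5.25, SE 0.45), the proteoglycan gene Epyc (3.82, SE 0.23), the growth factor gene Igf1 (3.43, SE 0.32), Anxa2 (3.39, SE 0.29), Ecrg4 (3.14, SE 0.39) and Lum (2.99, SE 0.39). Lower cochlear trends were those of Spag6l (-4.16, SE 0.28), Smpx (-3.88, SE 0.30), Ap3b2 (-3.67, SE 0.45), Gfi1 (-3.33, SE 0.22), Hey2 (-3.20, SE 0.29) and Espn (-3.03, SE 0.58). Hmga2 had the higher trend in the cochlea (2.74, SE 0.30), and Myo7a (-2.03, SE 0.30) and Myo6 (-2.01, SE 0.27) the lower. For Atoh1 the trends did not differ past the threshold (0.14, SE 0.19), and the sign turned at a pseudocount of 64 (-0.40) and without replicate 1 of the E15 cochlea (-0.04).

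The difference in trend of hair cell genes was downward in 10 of 20 and upward in none (1.14e-13), including Otof (-2.13, SE 0.28), the gene of the synaptic protein otoferlin. Genes of cell cycle exit had 4 higher and 1 lower of 13 (0.2469), with Cdkn1b at 1.98 (SE 0.39), Btg1 at 1.66 (SE 0.25) and Cdkn2d at -1.60 (SE 0.20), the median of the list at -0.01, its mean at 0.26 and its test upward. Cell cycle genes were lower in 3 of 36, Aurkb the most (-1.11, SE 0.18), and the list was called (0.0082; adjusted p = 0.4892 with an estimated correlation) but not without replicate 1 of the E14.5 cochlea (0.0507), of the E15 cochlea (0.3799) or of the E15 saccule (0.0583). Periotic mesenchyme genes had 3 higher and 1 lower of 22 (0.2469), with Dcn at 1.35 (SE 0.26) and Postn at -1.75 (SE 0.26). At a pseudocount of 64 none of the 3 lower cell cycle genes passed, Aurkb at -0.97, Bub1 at -0.87 and Kif11 at -0.73. Without replicate 1 of the E12.5 cochlea (Bub1 -0.88, Kif11 -0.88) or of the E15 cochlea (-0.82 and -0.92) only Aurkb passed. The E14 arrays belong to all 3 tissues here, and without them 359 genes passed.

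**Figure D4:**
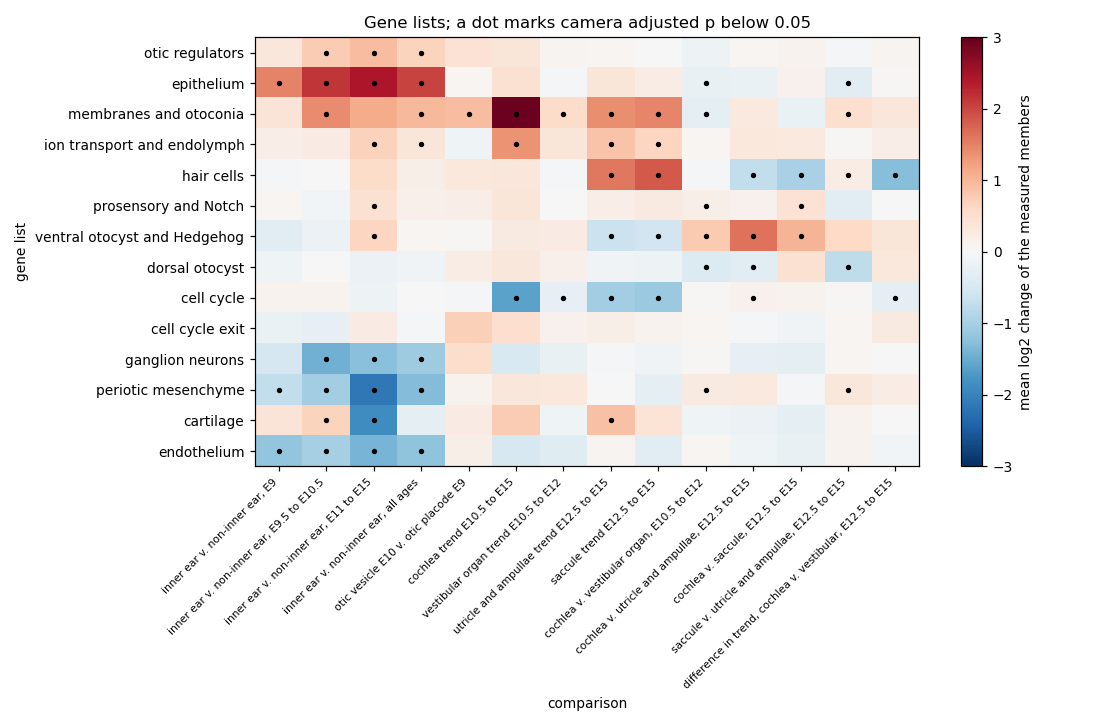
Mean log2 change of the measured members of 14 gene lists (vertical axis) in the 14 comparisons (horizontal axis) as a color from blue (lower) to red (higher), with a dot where the camera adjusted p is below 0.05. In the difference in trend 10 of 20 hair cell genes are lower and none higher, against 13 of 20 risen in the saccule.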

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

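The tests of the E14 arrays, of globin and erythroid genes, of mesenchyme and of later onset, the hair cell test without the E14 arrays, the change between early and late stages and the count of unnamed probe sets were chosen after the results had been seen, while the other splits were chosen before.

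Trends from E12.5 to E15 differed between the cochlea and the vestibular tissues in 348 genes, a difference between groups that was itself tested. The cochlea also differed from the vestibular tissues in another way late (E12.5 to E15) than early (E10.5 to E12): a test of that change called 410 genes, 192 with a more positive and 218 with a more negative late difference. Late differences here are against the mean of the saccule and the utricle with ampullae. Dlx1 moved from -3.17 to -0.04 (change 3.12, SE 0.35), Irx3 from 0.39 to 3.24 (2.85, SE 0.20), Cyp26a1 from 1.47 to 4.21 (2.74, SE 0.20), Ces1d from 0.28 to 2.85 (2.57, SE 0.17) and Slit3 from -0.97 to 1.57 (2.53, SE 0.11). For Dlx1 the saccule lay far below the utricle with ampullae (-5.49, SE 0.23). Its late -0.04 therefore averages opposite differences and does not mean that Dlx1 stopped differing between these tissues. Gfi1 moved from -0.05 to -3.63 (-3.58, SE 0.13), and Nefm (-2.88, SE 0.40), Nefl (-2.42, SE 0.23), Sel1l2 (-2.37, SE 0.76) and Ddx25 (-2.30, SE 0.15) moved the same way. Crabp1 alone passed in opposite directions, -1.05 early and 1.08 late (change 2.12, SE 0.26). The early vestibular organ is not the same dissection as the late saccule and utricle with ampullae, and the E10.5 arrays had the shorter dispase time, so these changes mix stage with tissue. The early cochlea and vestibular organ arrays also differ in deposited scale. The genes named are the 5 with the largest change each way and Crabp1, chosen by their values.

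Probe sets without a gene name are used in no comparison, yet some were higher in the inner ear than in the surrounding tissue: 29 at E9, 38 at E9.5 to E10.5 and 60 at E11 to E15, of 822 kept, against 21, 22 and 48 lower. The highest reached log2 2.87, 3.83 and 2.46. Of the 9352 named genes 253, 348 and 792 were higher and 302, 438 and 668 lower in the same windows. The shares are of similar size, so unnamed probe sets do not stand out from named genes.

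Hair cell genes rose less in the cochlea than in the vestibular tissues in 10 of the 20 measured. Against more mesenchyme in the later cochlea dissections, the epithelial list had a median difference in trend of 0.06, where dilution would lower it with the hair cell genes. The error of that median, 0.13, comes from the spread over its 20 genes taken as independent, so its precision over arrays is not known. Periotic mesenchyme genes themselves went both ways (3 higher and 1 lower of 22, with Lum at 2.99, Dcn at 1.35 and Postn at -1.75). Against the E14 arrays as the source, 10 hair cell genes were lower without those arrays and 10 with them. A later onset in the cochlea cannot be told apart from none, because Atoh1 rose there by 2.24 (SE 0.16) from E12.5 to E15 but about as much in the utricle with ampullae (2.20) and the saccule (2.00), with a difference in trend of 0.14 (SE 0.19). A lower share of hair cells in the cochlea, a difference of the tissue itself, stays open and was not tested.

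The arrays of E14 stood apart from those of E13.5 and E14.5 in all 3 tissues, with 182 genes off by more than 1 log2 in at least 2 tissues against 3 at E13, 12 at E13.5 and 38 at E14.5. Deviations at E14 correlated between tissues across genes at 0.64 to 0.79. At E13.5 (0.44 to 0.67) and E14.5 (0.42 to 0.67) the E14 arrays are among the neighbours, so those values are not independent of E14. At E13, where they are not, the correlations were 0.05 to 0.25. At E11 the cochlea and the vestibular organ gave 0.84. Lowest were Lep (-2.40), Gas5 (-2.02), Hbb-y (-1.95), Atp5e (-1.89), Timm10b (-1.88) and Ndufa3 (-1.87), genes picked by their values. A candidate explanation is a lower yield of ribosomal protein and respiratory chain transcripts in the E14 RNA, whose median was -0.62 in the cochlea, -0.80 in the utricle with ampullae and -0.47 in the saccule. These classes were chosen after the values were seen and include Atp5e and Ndufa3, so their medians describe the pattern and do not test its cause. A change of the stage itself cannot be told apart from such a lower yield, since the falling genes deviated by similar amounts on both arrays of the cochlea (-1.22 and -1.09) and saccule (-0.96 and -0.67) but by a ratio of 2.44 between those of the utricle with ampullae (-2.34 and -0.96). Replicate 2 of each tissue at E14 is among the 10 arrays with high Fem1b, and replicate 1 is not. Lnx2, also high on those 10 arrays, was among the genes higher at E14. In each tissue the falling genes deviated more on replicate 1, so their fall is not confined to arrays with high Fem1b. How far this difference between the replicates adds to the E14 pattern was not tested. Dates of RNA preparation or hybridization are not given in the sources used here.

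Embryonic globin genes fell in the cochlea, saccule and utricle with ampullae while the adult gene Hbb-b2 rose in the cochlea and the utricle with ampullae, although epithelium was dissected. A switch to adult globin in blood carried over may explain the fall, since Hbb-b2 was 4.48 higher (SE 0.79, adjusted p = 3.24e-05) in surrounding tissue of E11 to E15 than of E9.5 to E10.5. Fewer red blood cells in later dissections stay open, because Hbb-b2 rose by 3.18 in the cochlea and 2.68 in the utricle with ampullae but did not pass in the saccule (1.19, SE 0.67), and a steep switch could outweigh a loss of cells. More blood stays open too: the erythroid genes other than globins had a median cochlea trend of -0.10 (error 0.43, from the spread over 5 genes and not over arrays), but at E11 to E15 they did not follow the globin genes, which were lower in the inner ear than around it (Hbb-b2 -3.22, Hba-x -3.62, Hbb-bh1 -3.81, Hbb-y -2.59) while the erythroid median differed by 0.26. That last comparison was added after its values were seen, and without it the test would have spoken against more blood.

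Among 100 splits of the arrays for each comparison named below in this paragraph, the real split included, only the real one, 1 of 100, gave as many genes. A split as large by chance can be excluded at that level only if the arrays are unpaired. For the comparisons with the saccule, whose arrays may be paired, no splits that part every pair were run. No splits were run for the single windows of the inner ear, for E10 against E9 or for the trends of single tissues. In the cochlea against the utricle with ampullae equal numbers were taken to pair the arrays. There the real split was also the only 1 as large among 100 splits that part every pair, with 286 genes against at most 229 in the others. This was tested after the first splits were seen. In a simpler model the real counts and the highest of the others were 639 and 125 for the inner ear against its surroundings over all ages, 132 and 2 for the cochlea against the vestibular organ, 286 and 26 against the utricle with ampullae, 354 and 111 against the saccule, 253 and 113 for the saccule against the utricle with ampullae, and 199 and 2 for the difference in trend.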

How the results depend on the processing

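Fits without the E14 or E11 arrays, with a term for the arrays with high Fem1b and within 1 dispase time were chosen after seeing the data; the other settings were planned. Of 476 gene results fixed by the naming rule, 423 kept direction and side of the threshold in every planned setting other than leaving out arrays, and of 84 list results 59 did. No filter (474 of 476 gene results unchanged), only the groups of a comparison (474), the Fem1b term (474), a pseudocount of 1 (467) and values as deposited (467) moved few. Array weights (475) and every probe set alone (475) could move few by construction. The 2 arrays of each group received equal weights. With probe sets alone, a gene was scored by its probe set with the smallest p-value, so the agreement of its probe sets was not tested. At a pseudocount of 64, which shrinks changes of small signals by construction, there were 38 gene results whose call ended, and all counts fell by more than 1.5 times: to 276 (E9), 458 (E9.5 to E10.5), 937 (E11 to E15) and 334 (all ages) for the inner ear against its surroundings, 260 for E10 against E9, 914, 204, 426 and 420 for the trends of cochlea, vestibular organ, utricle with ampullae and saccule, 63, 188 and 208 for the cochlea against vestibular organ, utricle with ampullae and saccule, 162 for the saccule against the utricle with ampullae, and 205 for the difference in trend. The cochlea against the vestibular organ had 202 genes at a pseudocount of 1 and 218 as deposited, and E9 had 987 as deposited; the cause was not tested, beyond the shift of all genes given with those comparisons. Within 1 dispase time the cochlea against the vestibular organ had 232 genes at E10.5, and the vestibular organ trend 238 from E11, over fewer stages and days. Atoh1 in the difference in trend turned to -0.40 at a pseudocount of 64 and ranged from -0.04 (without replicate 1 of the E15 cochlea) to 0.32 when arrays were left out. The direction of the test turned for some lists, none of them called, whose means there were 0.05 for neural crest genes at E11 to E15 and 0.31 for periotic mesenchyme in the cochlea against the saccule (filter of 16 arrays), -0.04 (only the groups of the comparison) and -0.24 (E11 and later) for retinoic acid genes in the vestibular organ, and 0.05 (pseudocount 64), 0.04 (only the groups of the comparison) and 0.03 (without replicate 1 of E12.5, in a range of 0.01 to 0.08 over the arrays left out) for the same genes in the utricle with ampullae. The cause was not tested for these.

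An estimated correlation ended 15 list calls and the filter of 16 arrays 4, under which the hindbrain list at E9 had too few members for a test. Leaving out each array, with the lone array of its group assumed to vary like the other groups, left counts within 1.5 times, at 467 to 566 (E9), 753 to 821, 1452 to 1602 and 531 to 573 (all ages) for the inner ear, 475 to 613 for E10 against E9, 1329 to 1537, 329 to 380, 556 to 988 and 628 to 742 for the trends in the order above, 124 to 148, 281 to 294 and 342 to 369 for the cochlea comparisons, 249 to 264 for the saccule against the utricle with ampullae and 285 to 486 for the difference in trend. Of 10682 gene values with 1 array left out, 64 lost their call. Except for the cochlea with the utricle and ampullae, arrays with the same number at a stage are taken to share only a number: over 22 pairs of tissues their deviations correlated across genes at -0.5 to 0.57, above 0.1 in 18 and below -0.1 in 2, the saccule at E15. For the saccule this is an assumption, since it correlated above 0.1 with the cochlea and with the utricle with ampullae at 5 of 6 stages each. At E15 the high Fem1b signal lies on replicate 2 of the saccule but on replicate 1 of the other tissues. Pairing of the saccule arrays, with crossed numbers at E15, therefore cannot be excluded. A term for the replicate number gave 557, 786, 1460 and 543 genes for the inner ear windows, 498 for E10 against E9, 1398, 381, 705 and 662 for the trends, and within each stage 134, 287, 354, 254 and 364 for the tissue comparisons and the difference in trend. It ended no gene call and 6 list calls: retinoic acid genes in the cochlea against the utricle with ampullae, the only call changed there, epithelium in the cochlea against the vestibular organ (adjusted p = 0.0675), hair cells, membranes and periotic mesenchyme in the saccule against the utricle with ampullae (0.0605, 0.0605 and 0.0671) and skeletal muscle at E11 to E15 (0.0508). Signals under about the pseudocount are compressed and 5.43 to 12.04 percent of the values of an array are at the floor, so differences between weakly expressed genes were not detectable at this signal.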

Other observations

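The lists were fixed beforehand and chosen for this text after their results were seen, and the set of arrays with high Fem1b was defined after the values were seen.

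Beside the mesenchyme, the tissue around the inner ear at E11 to E15 carried genes of blood vessels and muscle (48 arrays of inner ear against 2). Endothelial genes were lower in the inner ear in 8 of 11 and higher in none (camera adjusted p = 7.05e-06), among them Vwf (-3.87, SE 0.29), Cdh5 (-1.93, SE 0.18) and Emcn (-1.88, SE 0.17). Skeletal muscle genes were lower in 4 of 8 (0.0471; adjusted p = 0.1636 with an estimated correlation), with Tnnc2 at -3.67 (SE 0.30) and Myog at -2.20 (SE 0.30). That list was also lost without each of 6 single arrays, most of all replicate 2 of the surrounding tissue (adjusted p = 0.0952). Epidermis genes were lower in 3 of 9 and higher in 1 (0.1014): Trp63 (-3.27, SE 0.42; -0.25 at a pseudocount of 1, where another probe set represents it) and Krt15 (-1.54, SE 0.25) against Perp (2.27, SE 0.31). FGF genes were lower in 3 of 17 and higher in 1 (0.2729): Fgf9 was higher (2.54, SE 0.15), Fgf18 (-1.61, SE 0.22) and Fgf3 (-1.34, SE 0.20) lower. Neural crest and glial genes went both ways, 2 higher and 3 lower of 12 (0.6405): Erbb3 (3.78, SE 0.12) and Sox10 (2.29, SE 0.19), which otic epithelium also expresses, against the melanocyte gene Pmel (-2.11, SE 0.33).

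Neuronal genes did not move together in the late vestibular tissues. In the utricle with ampullae Nefl rose (2.83, SE 0.31) while Neurod1 (-1.83, SE 0.19) and Tubb3 (-1.57, SE 0.33) fell, 2 up and 3 down of 21 ganglion neuron genes (0.8463). In the saccule Nefl rose by 2.77 (SE 0.31) and Neurod1 fell (-2.75, SE 0.19), again 2 up and 3 down (0.6267), with a median of 0.02, a mean of -0.10 and a downward test. Nefm, which rose in the utricle with ampullae (1.60, SE 0.55) and the saccule (1.97, SE 0.55), was lost without single arrays (adjusted p 0.0677 to 0.1592 and 0.0600). Against the utricle with ampullae the late cochlea had 3 of these genes lower and 1 higher (0.3155), with Nefm at -3.05 (SE 0.27) and Nefl at -2.27 (SE 0.15). Retinoic acid synthesis genes rose in the utricle with ampullae, Aldh1a1 by 2.93 (SE 0.23) and Aldh1a2 by 2.82 (SE 0.40), as the binding protein gene Crabp1 (-2.83, SE 0.36) and the degradation gene Cyp26a1 (-1.74, SE 0.28) fell, with a list median of -0.22, a mean of 0.04 and a downward test (0.9067). Immediate early genes rose in 5 of 17 there (0.2644) and in 4 of 17 in the saccule (0.1637), with Fos at 2.00 (SE 0.20) and 2.21 (SE 0.20) and Klf4 at 1.16 (SE 0.17; 0.97 at a pseudocount of 64) and 1.61 (SE 0.17), none of them fallen.

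On 10 arrays Fem1b had a log2 signal of 10.57 to 11.60 against at most 10.04 on the other 54, and Evpl one of 4.70 to 5.26 against 5.73 to 7.40. They are replicate 2 of the E10 otic vesicle, replicate 1 of the cochlea and of the vestibular organ at E10.5, replicate 2 of each tissue at E14, replicate 1 of the cochlea and of the utricle with ampullae and replicate 2 of the saccule at E15, and replicate 2 of the surrounding tissue of E9.5 to E10.5. What these samples share is not given in the sources used here. With a term for them each count stayed within 1.5 times, the utricle with ampullae trend at 614 genes, but 3 list calls ended, all in the saccule against the utricle with ampullae (hair cells, membranes and otoconia, periotic mesenchyme), and so did the call of Slc2a3 (-0.97). Lnx2 was high on these 10 arrays too (6.43 to 9.26), but also on every array of E11 to E12 (7.07 to 9.38). The surrounding tissue of E11 to E15 had 7.67 and 8.60, against at most 6.47 on all remaining arrays. Those E11 to E12 and surrounding-tissue arrays enter the cochlea and vestibular organ trends, the early differences and the E11 to E15 inner ear comparison. No term for them was fitted, and whether stage or handling set them apart was not tested.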
